A study of Escherichia coli with 6 samples.

How the data were processed

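Total RNA of Escherichia coli K-12 strain AB1157 was measured on 6 single-colour Affymetrix arrays, 3 of wild-type cells and 3 of cells carrying the nusA11 allele of nusA. AB1157 is a K-12 derivative long used in work on DNA repair, and nusA encodes NusA, a factor that binds RNA polymerase and acts in transcript elongation, pausing and termination. Per the labels' protocols, RNA was purified with a Qiagen column kit and biotin was added to the cDNA by terminal labelling. Growth medium, temperature and growth phase are not given in the sources used here.

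The deposited table holds 1 log2 expression value per probe set and array, which the authors made with RMA, per the submitters' processing notes. RMA corrects the background, gives all arrays the same distribution of probe intensities and summarises the probes of a probe set. Its version and settings are not given in the sources used here. Because the arrays were scaled to a common distribution, a shift of most transcripts in 1 direction would be partly removed, and each difference is relative to the bulk of the probe sets. Array medians over all probe sets lay between 8.07 and 8.13, and the number of arrays limits the precision.

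The table has 7312 probe sets. Of these, 4345 carry a locus tag in their identifier, 2886 are intergenic, 59 are for phage and plasmid sequences and 22 are array controls. The platform annotation gives 1 gene symbol for 3804 probe sets, several for 594 and none for 2914. A probe set was named where the locus tag in its identifier was a gene of the MG1655 reference table and the annotation's MG1655 gene identifiers pointed to that gene alone. This named 4101 probe sets, each for a different gene, including 544 for which the annotation lists several symbols, mostly from other strains. The other 244 probe sets with a locus tag stayed unnamed and outside the gene comparison. Of the named probe sets, 69 are of the kinds that the array design marks as shared between similar sequences. Genome coordinates of intergenic probe sets are those in their identifiers, and the build is not given in the sources used here.

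Genes were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, strain as the only term, both directions), with Benjamini-Hochberg adjustment over the 4101 genes and a threshold of 0.05 on the adjusted p. Differences are nusA11 minus wild type on the log2 scale with their standard error (SE), and "rose" and "fell" are used for features past the threshold. Intergenic probe sets were fitted and adjusted separately, and their changes under each alternative are given as percent of the probe sets tested. Gene lists were tested with limma's camera, which asks whether the genes of a list moved relative to all others, with a preset inter-gene correlation of 0.01 and adjustment over the 38 lists that had at least 4 measured genes. Beside it, fry asked whether the genes of a list moved on balance in 1 direction, and its mixed form whether they changed in either direction, neither in comparison with other genes.

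The tests, the lists and the rule for named genes were fixed before the data were examined. The rule names the measured genes of the nusA operon, the 8 largest rises and 8 largest falls among genes past the threshold whose 3 nusA11 values lay on the same side of all 3 wild-type values, and up to 4 members with the smallest p of each list. The 39 lists cover the nusA operon, transcription factors of elongation, DNA repair, stress responses, translation, amino acid synthesis, motility and surface structures, central and respiratory metabolism, sugar use, toxin-antitoxin pairs, prophages, and genes of the gpt-proA region, deleted in AB1157 by its textbook genotype. A further 13 lists were chosen after the values were seen and are used in the closing section alone.

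Alternatives were a replicate block, moderation with trend and robust settings, no moderation, median centring, cyclic loess, array quality weights, a filter on the dimmest 25% of probe sets, every probe set on its own, and leaving out each array in turn. For the lists, an estimated correlation and fry were tried. Centring and cyclic loess were applied to genes and intergenic probe sets separately. Chosen after seeing the data were the same 2 scalings of both together, other choices of probe sets, centring on the phage and plasmid probe sets, and the added lists. A planned mean over the probe sets of a gene was not run, since each gene has 1 probe set.

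The steps were tested on simulated data. With the means and spreads of the 4101 genes and 200 of them changed, 43.3% of changes of 0.5 on the log2 scale, 89.6% of changes of 1 and 100% of changes of 2 were recovered, and 6.06% of the calls were false. With the 2886 intergenic probe sets the shares were 61.2%, 86.6% and 97.0%, with 6.32% false calls. Of 3 lists shifted by 0.5, camera called 3, and it also called 1 of 34 lists that were not shifted and shared no gene with them. The simulated noise was drawn gene by gene, with the same spread in both strains. It holds no correlation between genes, so it cannot show how often camera calls unshifted lists whose genes vary together. Figures were drawn with matplotlib 3.10.9.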

Results

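The 6 arrays compared wild-type AB1157 cells with cells of the nusA11 mutant, 3 arrays each. The series title places the study in the roles of NusA in DNA repair and in the tolerance of DNA damage, and the comparison asks how transcript levels differ between the strains. The labels do not say that the replicates were separate cultures, so p-values measure only the spread between these samples, which may be technical. Over the named genes, arrays correlated at r = 0.991 to 0.997 within the wild type, at 0.979 to 0.991 within nusA11 and at 0.930 to 0.944 between the strains. The first principal component held 78.5% of the variance and separated the strains. The second held 11.6% and set nusA11 replicate 2 apart from the other arrays. The median SD over genes was 0.08 on the log2 scale in the wild type and 0.16 in nusA11.

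In nusA11, genes for respiration with nitrate and nitrite had the largest rises. Genes for the uptake of xylose and galactose, for acetate use and for the TCA cycle and glyoxylate shunt had the largest falls. Transcripts of nirB, which encodes the large subunit of cytoplasmic nitrite reductase, rose by 4.09 ± 0.13 (log2, SE, n = 3 per strain). The nitrate reductase operon genes narG, narH and narJ rose by 4.07 ± 0.27, 3.76 ± 0.22 and 3.31 ± 0.17. In the formate-dependent nitrite reductase operon, nrfB rose by 3.90 ± 0.12 and nrfA by 3.04 ± 0.11. The other 2 of the 8 largest rises were malK, for the ATPase of the maltose transporter, at 3.73 ± 0.16, and treB, for trehalose uptake, at 3.18 ± 0.23. The largest fall was in xylF, the xylose-binding protein gene, which fell by 4.32 ± 0.15. The acetate gene yjcH fell by 3.89 ± 0.23 and acs fell by 3.06 ± 0.16; the 2 genes share an operon with an acetate transporter gene. The glyoxylate shunt genes aceB and aceA fell by 3.59 ± 0.48 and 3.32 ± 0.35. The succinate dehydrogenase genes sdhC and sdhD fell by 3.45 ± 0.14 and 3.16 ± 0.16, and mglB, the galactose-binding protein gene, fell by 3.10 ± 0.16. In 12 of the 16 genes the lower of the 2 strain levels was at or below 9.45, the highest level of phage and plasmid probe sets, and for yjcH in nusA11 (6.79) it was below their median of 7.37. The sizes and ranks of these changes are therefore not exact. Limma's Benjamini-Hochberg adjusted p for these 16 genes ran from 6.09e-07 for nirB and nrfB to 0.000786 for aceB.

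**Figure D1:**
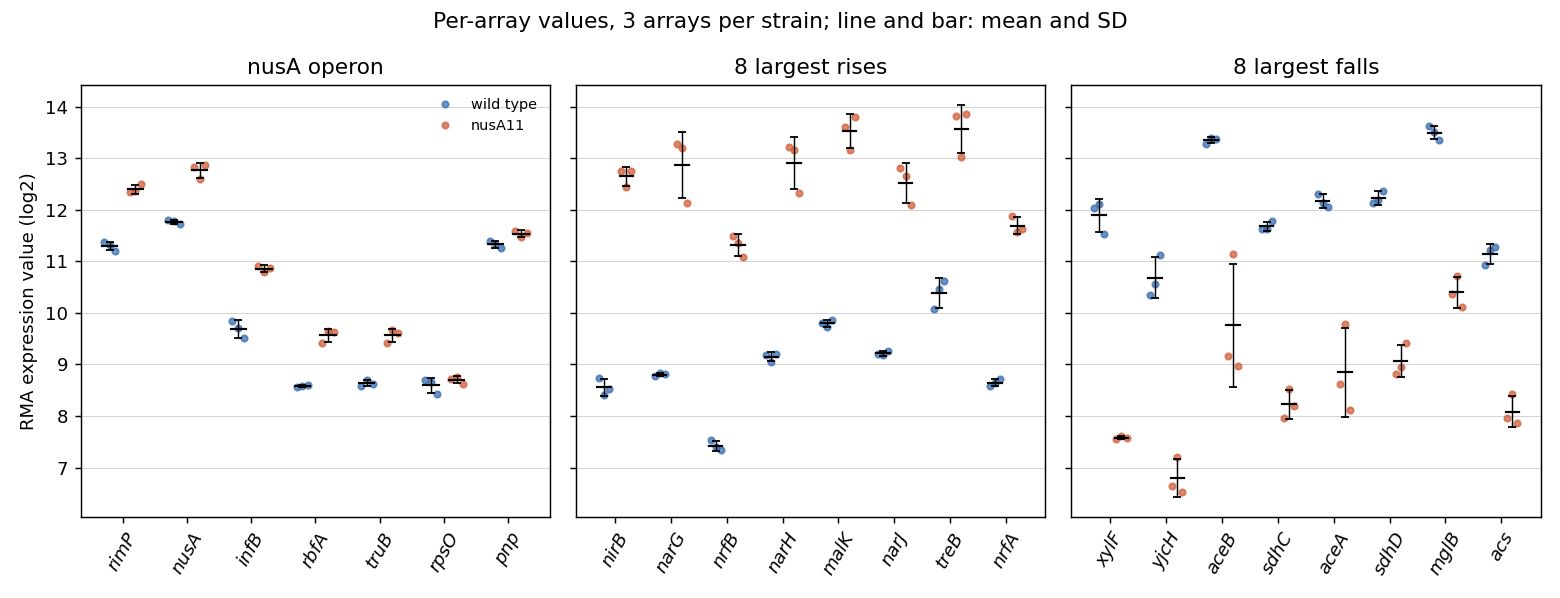
RMA expression values (log2, vertical axis) of the measured genes of the nusA operon, the 8 largest rises and the 8 largest falls. Points are single arrays, 3 of wild type in blue and 3 of nusA11 in orange, and the line and bar are mean and SD; the nusA11 values of aceB lie between 8.97 and 11.14, all below the wild-type values of 13.29 to 13.39.

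Over all 4101 named genes, 1090 changed, of which 518 rose and 572 fell (limma, Benjamini-Hochberg). At least 2-fold changes past the threshold numbered 138 upward and 153 downward. At an unadjusted p under 0.05 there were 1606 genes. In 1870 genes the groups did not overlap, where chance gives 10% of genes, and 1087 of the changed genes were among them. The median difference over all genes was -0.05, and it became 0.13 when each array was centred on its phage and plasmid probe sets, a setting chosen after seeing the data, under which 762 genes rose and 260 fell. Without wild-type replicate 2, 664 genes changed.

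The nusA transcript itself was higher in the mutant. It rose by 1.00 ± 0.10 (limma adjusted p = 0.000167, n = 3 per strain), with values of 12.60 to 12.86 in nusA11 against 11.72 to 11.80 in the wild type. A transcript level does not check the strain labels here, since an altered allele can still be transcribed. Of 7 measured genes of the nusA operon, 5 rose: nusA, the ribosome maturation gene rimP (1.10 ± 0.10), the initiation factor gene infB (1.17 ± 0.11), rbfA (0.98 ± 0.10) and truB (0.93 ± 0.10). The last genes of the operon did not pass the test: rpsO differed by 0.11 ± 0.10 and pnp by 0.21 ± 0.09, with adjusted p of 0.466 and 0.127. Adjusted over the list alone, 5 rose as well. As a list the operon was higher than other genes (camera adjusted p = 5.44e-05, and adjusted p = 0.385 with an estimated correlation). Among the 19 measured genes within 10 locus tags on either side of the operon, 1 rose and 3 fell, with a median of -0.14. Of 13 genes for RNA polymerase and elongation or termination factors, 4 rose, adjusted over the list alone also 4. They were nusA, rpoA for the alpha subunit (0.59 ± 0.16), greA for a transcript cleavage factor (0.47 ± 0.12) and rpoZ for the omega subunit (0.38 ± 0.09); camera gave an adjusted p of 0.106 and fry of 0.0432. Here and below, 6 counts in a series are those without wild-type replicates 1, 2 and 3 and nusA11 replicates 1, 2 and 3, in this order. Of these 13 genes 2, 1, 1, 5, 5 and 2 rose, and without nusA11 replicate 3 also 1 fell. The list passed camera without nusA11 replicate 1 (adjusted p = 0.0274).

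Genes of anaerobic respiration and fermentation rose together. Of 35 measured, 30 rose and 0 fell, with a median of 1.29 (camera adjusted p = 7.25e-20, and adjusted p = 0.234 with an estimated correlation). Besides nirB, nrfB and nrfA, nirD, for the small subunit of nitrite reductase, rose by 2.78 ± 0.11. Adjusted over the list alone, 31 rose. Genes of the TCA cycle and its glyoxylate branch fell: 16 of 16 measured, also when adjusted over the list alone, with a median of -1.57 (camera adjusted p = 1.39e-10, and adjusted p = 0.0995 with an estimated correlation). The falls included sdhB (1.98 ± 0.12) and fumA, for the aerobic fumarase, which fell by 1.77 ± 0.13. Among 29 genes of NADH dehydrogenase, terminal oxidases and ATP synthase, 6 fell and 0 rose, with the same counts adjusted over the list alone. Members of the cytochrome bo oxidase operon, which serves respiration with ample oxygen, led them: cyoA, cyoB, cyoC and cyoD had differences of -1.86, -1.72, -1.77 and -1.92. That list had a camera adjusted p of 0.106 and a fry adjusted p of 0.0251. It passed camera without nusA11 replicate 3 (0.0337), and without nusA11 replicate 2 also 2 genes rose. Of 8 ribonucleotide reductase genes, 2 rose, adjusted over the list alone also 2, namely nrdD (1.96 ± 0.10) and nrdG (1.21 ± 0.11), which encode the oxygen-sensitive enzyme and its activase. The aerobic nrdA differed by 0.28 ± 0.12 (adjusted p = 0.121) and the list as a whole had a camera adjusted p of 0.150 and a fry adjusted p of 0.0148.

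Sugar transport and catabolism genes changed in both directions. Of 48 measured, 18 rose and 8 fell, or 18 and 9 adjusted over the list alone. Besides malK and xylF, the maltose gene malF rose by 2.33 ± 0.10 and the xylose gene xylG fell by 2.47 ± 0.12. The median was -0.07 and the mean 0.20, and camera pointed upward with an adjusted p of 0.181. The median was -0.14 without nusA11 replicate 1 and 0.06 without nusA11 replicate 2. In the tryptophanase operon, too small for a list test, tnaA fell by 0.95 ± 0.10, while tnaC and tnaB differed by -0.33 ± 0.13 and -0.21 ± 0.15 with adjusted p of 0.0928 and 0.332. Adjusted over the list alone, 2 of its 3 genes fell.

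**Figure D2:**
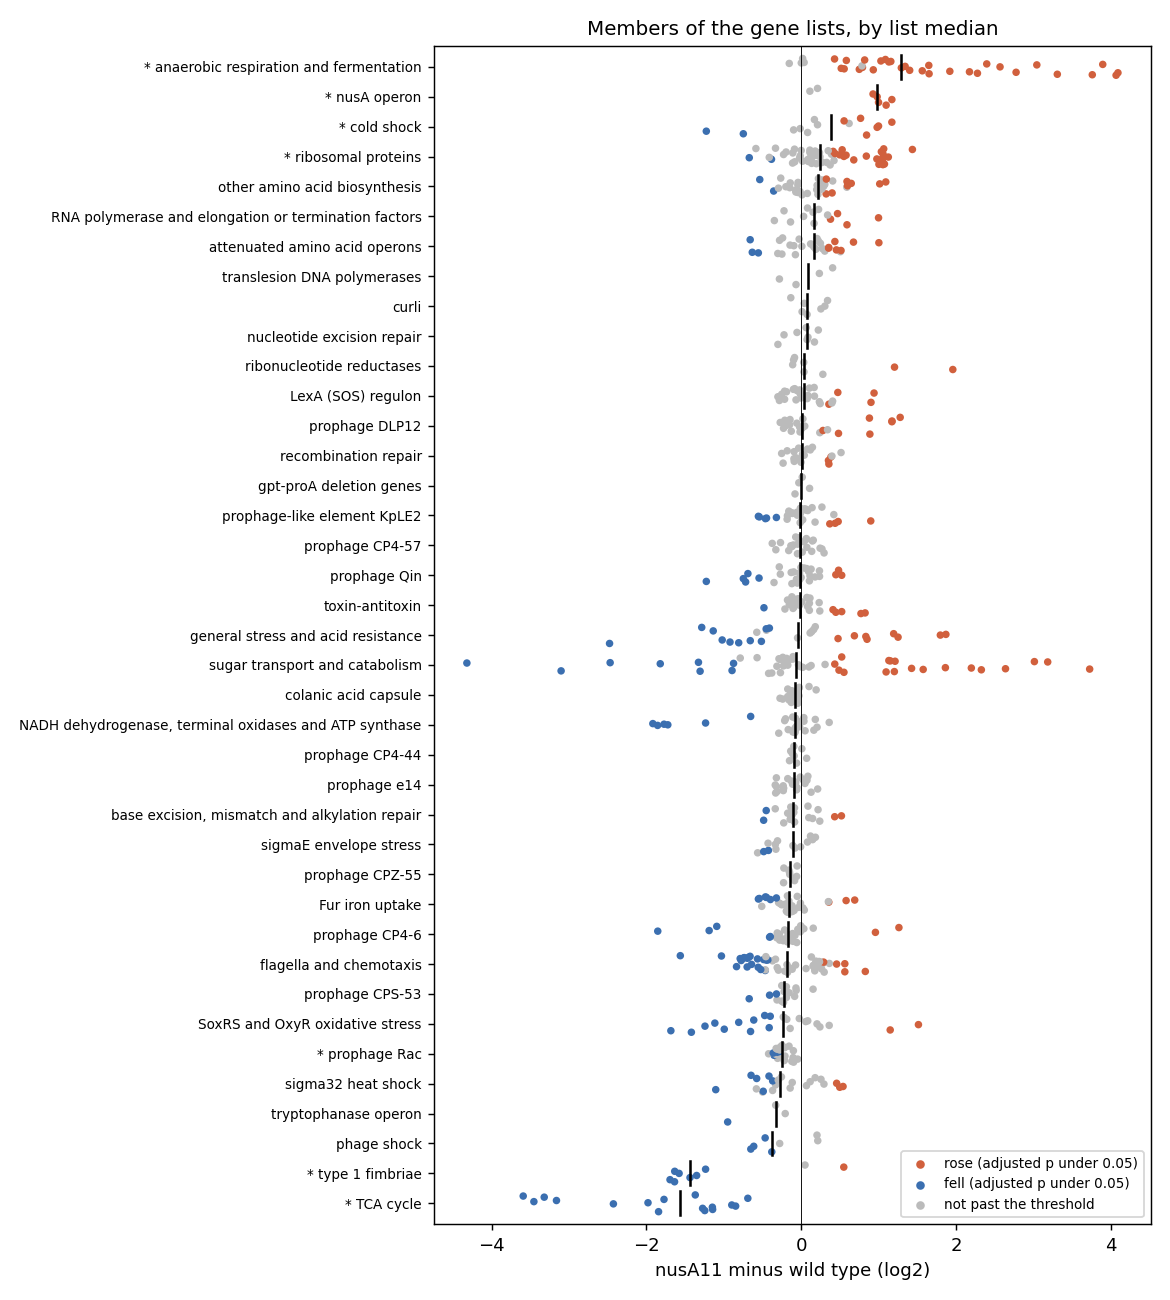
Differences (nusA11 minus wild type, log2, horizontal axis) of the measured genes of 39 lists, 1 point per gene, ordered by list median (black line). Orange and blue mark genes that rose and fell, grey marks the rest, and an asterisk marks the 7 lists past the camera threshold; the TCA cycle median lies at -1.57 and the anaerobic respiration median at 1.29.

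Few genes of DNA repair and of the SOS response, which the study's title concerns, passed the test, and their number depended on single arrays. Of 28 measured genes of the LexA (SOS) regulon, 4 rose and 0 fell: yebG (0.94 ± 0.12), the division inhibitor gene sulA (0.90 ± 0.23), sbmC (0.47 ± 0.14) and recA (0.36 ± 0.11), with limma adjusted p from 0.000477 to 0.0431. Adjusted over the list alone, 1 rose, and the list had a camera adjusted p of 0.324. With 1 array left out, 2, 2, 1, 2, 9 and 1 rose, in the order wild-type replicates 1 to 3 and nusA11 replicates 1 to 3, and 1 fell without the last. Among 8 genes of nucleotide excision repair, 0 passed in limma, also when adjusted over the list alone (camera adjusted p = 0.861). An unadjusted limma p under 0.05 was found for 1 of them, uvrA, which differed by -0.30 ± 0.12 (adjusted p = 0.0883). The coupling factor gene mfd differed by -0.22 ± 0.10, uvrB by 0.17 ± 0.15 and polA by 0.22 ± 0.10. The translesion polymerase genes dinB, umuC, umuD and polB differed by -0.28, 0.23, 0.41 and -0.07, with adjusted p of 0.192, 0.228, 0.140 and 0.721. Thus 0 of 4 passed in limma, adjusted over the list alone 0, and 0 had an unadjusted p under 0.05 (camera adjusted p = 0.765). Of 20 recombination repair genes, recA, recF (0.35 ± 0.09) and recJ (0.38 ± 0.11) rose and 0 fell, adjusted over the list alone 0 rose (camera adjusted p = 0.407). The double-strand break repair gene recN was close to the threshold, at 0.40 ± 0.13 with an adjusted p of 0.0501. In base excision, mismatch and alkylation repair, 2 of 20 rose and 2 fell, the same when adjusted over the list alone. These were the glycosylase genes ung (0.52 ± 0.15) and nei (0.43 ± 0.11), and mutY and aidB, which fell by 0.49 ± 0.10 and 0.45 ± 0.09 (camera adjusted p = 0.765). The recombination calls were lost without any 1 wild-type array or nusA11 replicate 1, and without nusA11 replicate 3, 1 rose and 1 fell. The 2 rises in base excision, mismatch and alkylation repair were lost without wild-type replicate 1 or 2 or nusA11 replicate 1, and without wild-type replicate 3, 1 rose. Leaving out nusA11 replicate 2 instead, 6 recombination genes, 2 translesion polymerase genes and 1 nucleotide excision gene rose. The mixed form of fry, which asks for change in either direction, gave adjusted p of 0.00567 for the LexA regulon, 0.00502 for nucleotide excision, 0.0315 for recombination, 0.000117 for base excision, mismatch and alkylation, and 0.287 for translesion polymerases. By this form 31 of the 38 lists passed, so a pass does not set the repair lists apart from the others.

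Stress regulons moved in parts. Of 22 sigma32 heat shock genes, 3 rose and 6 fell, or 3 and 7 adjusted over the list alone: the chaperonin gene groL fell by 1.11 ± 0.17, htpX by 0.58 ± 0.10 and dnaJ by 0.49 ± 0.12, and the protease gene clpP rose by 0.50 ± 0.11 (camera adjusted p = 0.358). With 1 array left out, in the order wild-type replicates 1 to 3 and nusA11 replicates 1 to 3, 1, 1, 2, 1, 4 and 1 rose and 6, 2, 2, 2, 6 and 6 fell. In the cold shock list 6 of 14 rose and 2 fell, or 7 and 2 adjusted over the list alone. The list was higher than other genes (camera adjusted p = 0.0336, and adjusted p = 0.893 with an estimated correlation). It shares nusA, rbfA, infB and pnp with the nusA operon. Outside that operon cspA, infC and lpxP rose by 0.84 ± 0.20, 0.55 ± 0.12 and 0.77 ± 0.23, while cspI and cspB fell, by 1.23 ± 0.16 and 0.75 ± 0.22. Without wild-type replicate 2 or 3 or nusA11 replicate 1, 1 of its genes fell. Its call was lost after cyclic loess, at an adjusted p of 0.0799, and without wild-type replicate 3 or nusA11 replicate 3, at 0.0985 and 0.0672. Of 15 sigmaE envelope stress genes, rseA and rseB fell, by 0.49 ± 0.13 and 0.42 ± 0.11, adjusted over the list alone also 2. These calls were lost without wild-type replicate 2 or 3 or nusA11 replicate 1, while 4 fell without nusA11 replicate 3 and 2 rose without nusA11 replicate 2. The sigma factor gene rpoE differed by -0.56 ± 0.21 and the outer membrane assembly gene bamA by -0.43 ± 0.16 (adjusted p of 0.0835 and 0.0863; camera adjusted p = 0.491). In the phage shock list 4 of 7 fell, adjusted over the list alone 5: pspB by 0.65 ± 0.09, pspC by 0.61 ± 0.11, pspG by 0.47 ± 0.09 and pspA by 0.38 ± 0.09 (camera adjusted p = 0.139, fry 0.00747).

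Of 25 general stress and acid resistance genes, 8 rose and 10 fell, or 8 and 12 adjusted over the list alone. The periplasmic acid chaperone genes hdeA and hdeB rose by 1.80 ± 0.11 and 1.87 ± 0.10 and hdeD rose by 1.19 ± 0.09, while osmY, a gene of stationary phase and osmotic stress, fell by 2.48 ± 0.18. Median and mean were both -0.05 while camera pointed upward (adjusted p = 0.922). The median was -0.19 without nusA11 replicate 1 and 0.03 without nusA11 replicate 3. Among 23 genes of the SoxRS and OxyR oxidative stress responses, 2 rose and 11 fell, the same when adjusted over the list alone (camera adjusted p = 0.106). The peroxidase reductase gene ahpF rose by 1.51 ± 0.13 and zwf, of the pentose phosphate pathway, by 1.15 ± 0.11, while the fumarase gene fumC fell by 1.68 ± 0.15 and the thioredoxin gene trxC by 1.12 ± 0.15. In this list 7 fell without wild-type replicate 2 and 5 rose without nusA11 replicate 2, and camera passed without nusA11 replicate 3 (0.0337). Of 33 Fur iron uptake genes, 3 rose and 6 fell, the same when adjusted over the list alone (camera adjusted p = 0.181). The ferrous iron genes feoA and feoB rose by 0.58 ± 0.13 and 0.69 ± 0.15, and the ferric citrate genes fecA and fecE fell by 0.55 ± 0.12 and 0.46 ± 0.10. Of the iron genes 2 fell without wild-type replicate 1 and 2 without wild-type replicate 2.

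Ribosomal protein genes were higher as a list. Of 54 measured, 19 rose and 2 fell, or 20 and 3 adjusted over the list alone, with a median of 0.24 (camera adjusted p = 5.95e-05, and adjusted p = 0.893 with an estimated correlation). The smallest p belonged to rpsQ, rpmC, rpsC and rplP, neighbours in 1 operon, which rose by 1.44 ± 0.12, 1.13 ± 0.14, 1.06 ± 0.13 and 1.05 ± 0.16. By fry the list had an adjusted p of 0.170. Without wild-type replicate 1, 1 fell, without wild-type replicate 2 the falls were lost, and without wild-type replicate 3, 4 fell. Of 29 genes of amino acid operons controlled by attenuation, 7 rose and 3 fell, the same when adjusted over the list alone (camera adjusted p = 0.165). The isoleucine and valine genes ilvM and ilvE rose by 1.00 ± 0.10 and 0.67 ± 0.09, while ilvN and the tryptophan synthase gene trpA fell by 0.66 ± 0.12 and 0.63 ± 0.14. Among 36 other amino acid biosynthesis genes, 8 rose and 2 fell, or 9 and 2 adjusted over the list alone (camera adjusted p = 0.0688). The glutamate synthase genes gltB and gltD rose by 1.09 ± 0.17 and 0.59 ± 0.12, argE rose by 0.40 ± 0.09, and the serine hydroxymethyltransferase gene glyA fell by 0.54 ± 0.11. With 1 array left out, in the order wild-type replicates 1 to 3 and nusA11 replicates 1 to 3, 2, 2, 3, 4, 11 and 5 attenuated genes rose and 2, 1, 2, 4, 3 and 2 fell. Of the others 2, 3, 3, 4, 13 and 5 rose and 1, 1, 1, 1, 4 and 1 fell, and that list passed camera without wild-type replicate 1 (0.0263) and without nusA11 replicate 1 (0.0183).

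Type 1 fimbriae genes fell: of 9 measured, 7 fell and 1 rose, the same when adjusted over the list alone, with a median of -1.44. The list was lower than other genes (camera adjusted p = 0.000410, and adjusted p = 0.893 with an estimated correlation). The pilin gene fimA fell by 1.64 ± 0.10, fimI by 1.70 ± 0.12, the chaperone gene fimC by 1.44 ± 0.13 and the usher gene fimD by 1.35 ± 0.12. Of 53 flagella and chemotaxis genes, 5 rose and 19 fell, or 9 and 22 adjusted over the list alone (camera adjusted p = 0.181). The receptor genes aer, for energy taxis, trg and tsr fell by 1.56 ± 0.11, 1.03 ± 0.12 and 0.66 ± 0.09, and the response regulator gene cheY by 0.74 ± 0.10. In the same 6 fits, without wild-type replicates 1 to 3 and then nusA11 replicates 1 to 3, 2, 3, 3, 2, 15 and 2 rose and 15, 12, 14, 18, 18 and 17 fell. Among 7 curli genes 0 passed in limma, adjusted over the list alone 0, and 2 had an unadjusted p under 0.05 (camera adjusted p = 0.335), with csgC at 0.25 ± 0.09, csgF at 0.34 ± 0.14, csgD at 0.31 ± 0.18 and csgG at -0.14 ± 0.14. Leaving out nusA11 replicate 2, 2 curli genes rose. Among 21 colanic acid capsule genes 0 passed, adjusted over the list alone 0, and 1 had an unadjusted p under 0.05 (limma; camera adjusted p = 0.492), with wcaD at -0.27 ± 0.12, wzxC at 0.19 ± 0.09, wcaC at -0.24 ± 0.12 and gmd at -0.17 ± 0.10.

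Of 27 toxin-antitoxin genes, 5 rose and 1 fell, or 4 and 1 adjusted over the list alone. The pairs mazE and mazF rose by 0.77 ± 0.11 and 0.83 ± 0.13, and relB and relE, which lie in prophage Qin, by 0.45 ± 0.11 and 0.52 ± 0.13. The list median was -0.02 and its mean 0.08, and camera pointed upward with an adjusted p of 0.335. The median was -0.04 without nusA11 replicate 1 and 0.04 without nusA11 replicate 2. In this paragraph 6 counts in a series are without wild-type replicates 1 to 3 and then nusA11 replicates 1 to 3. Of the toxin-antitoxin genes 4, 3, 2, 3, 6 and 3 rose, and of these 6 fits the fall passed only in that without nusA11 replicate 2. In prophage DLP12, 7 of 24 genes rose and 0 fell, the same when adjusted over the list alone (camera adjusted p = 0.106). They included ybcW and ybcV (both 1.17 ± 0.09), the regulator gene appY (0.88 ± 0.11) and exoD (0.48 ± 0.09). These genes had a median level of 6.88, and 23 of 24 were at or below the highest level of the phage and plasmid probe sets, 9.45, with ybcV at 5.24 and appY at 4.36. Without nusA11 replicate 1, 2 fell, and without nusA11 replicate 3 the list passed camera (0.0317). In prophage CP4-6, 2 of 29 rose and 5 fell, the same when adjusted over the list alone (camera adjusted p = 0.106). There yagL rose by 1.26 ± 0.19, and yagG, yagH and yagN had differences of -1.85, -1.19 and -1.09. In series, 1, 1, 1, 1, 2 and 1 rose and 3, 3, 3, 7, 5 and 3 fell, and the list passed camera without nusA11 replicate 1 (0.0150). In prophage Qin, 3 of 31 rose and 5 fell, the same when adjusted over the list alone (camera adjusted p = 0.904), with ynfN and flxA falling by 0.72 ± 0.12 and 0.69 ± 0.12. In series, 2, 1, 1, 1, 3 and 2 of the Qin genes rose and 5, 3, 3, 3, 7 and 4 fell. In prophage CPS-53, 3 of 15 fell and 0 rose, adjusted over the list alone also 3 (camera adjusted p = 0.106, fry 0.0432). These were yfdI, yfdL and yfdM, with differences of -0.67, -0.41 and -0.32, and yfdT differed by -0.25 ± 0.10 (adjusted p = 0.0992). Of these 15 genes, 8 were at or below the median level of the phage and plasmid probe sets and 15 at or below the highest, and in series 1, 2, 1, 3, 4 and 2 fell. In the prophage-like element KpLE2, 4 of 30 rose and 5 fell, the same when adjusted over the list alone. The sialate transporter region gene nanY rose by 0.90 ± 0.14, and fecB fell by 0.54 ± 0.12 beside fecA and fecE. The element's median was -0.013 and its mean 0.0025, with camera upward at an adjusted p of 0.886, and in series 1, 1, 2, 4, 4 and 3 of its genes rose and 2, 2, 4, 3, 7 and 4 fell.

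Signals from prophage Rac were lower as a list. Of its 23 measured genes, 4 fell and 0 rose, adjusted over the list alone 0, with a median of -0.25 (camera adjusted p = 0.0125, and adjusted p = 0.893 with an estimated correlation). The median was -0.17 after cyclic loess and -0.07 with arrays centred on the phage and plasmid probe sets. The genes ydaT, ydaG, ydaU and ydaV fell by 0.36 ± 0.10, 0.35 ± 0.09, 0.31 ± 0.09 and 0.28 ± 0.09. These 4 calls were lost without any 1 of the wild-type replicates and without nusA11 replicate 3. The list's call was lost without nusA11 replicate 3, at an adjusted p of 0.0964, and without the dimmest probe sets, at 0.197. Of the 59 phage and plasmid probe sets, which have no target in this genome by the array's design, 14 fell and 0 rose, with a median of -0.16, and of 22 control probe sets 3 fell and 0 rose, with a median of -0.22. The Rac genes had a median level of 6.99, and 23 of 23 were at or below the highest level of the phage and plasmid probe sets, 9.45, as were 22 of 22 genes of prophage e14. Among the e14 genes 0 passed in limma, adjusted over the list alone 0, and 7 had an unadjusted p under 0.05 (camera adjusted p = 0.335), with ymfT at -0.32 ± 0.11, lit at -0.31 ± 0.11, ymfD at -0.33 ± 0.12 and stfE at -0.32 ± 0.12. Without nusA11 replicate 1, 4 e14 genes fell, without nusA11 replicate 3, 1 fell, and without nusA11 replicate 2, 1 rose. In the CP4 prophage that holds flu, in the prophage that holds intZ and in the CP4 prophage that holds abpB, 0 of 8, 0 of 9 and 0 of 22 genes passed, adjusted over the list alone 0 in each. An unadjusted limma p under 0.05 was found for 0, 0 and 4 of them (camera adjusted p of 0.701, 0.407 and 0.886). Their genes with the smallest p included flu at -0.15 ± 0.11, cbeA at -0.14 ± 0.08, yeeT at -0.11 ± 0.10, intZ at -0.23 ± 0.12, yffR at -0.22 ± 0.12, abpB at -0.33 ± 0.11 and yfjS at -0.38 ± 0.14. In the prophage with abpB 1 gene fell without wild-type replicate 1, and 2 rose and 1 fell without nusA11 replicate 2. Its median was -0.013 and its mean -0.0095, while camera pointed upward. The genes of the gpt-proA region, deleted in AB1157 by its textbook genotype, differed as follows: gpt by -0.08 ± 0.13, phoE by 0.11 ± 0.13, proB by -0.03 ± 0.13 and proA by 0.01 ± 0.14. Of these 4, 0 passed in limma, adjusted over the list alone 0, and 0 had an unadjusted p under 0.05 (camera adjusted p = 0.886, upward, with a mean of 0.0020 and a median of -0.0093).

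Over the 38 lists tested, 7 passed the camera threshold, 4 higher and 3 lower in nusA11. With a correlation estimated for each list, 0 passed, and 3 had an unadjusted camera p under 0.05, which were the nusA operon, the TCA cycle and the anaerobic list. By fry, 9 lists passed, and by its mixed form, which asks for change in either direction, 31. Over 13 alternatives the adjusted p ran from 1.80e-21 to 0.234 for the anaerobic list, from 1.85e-17 to 0.0995 for the TCA cycle and from 2.18e-05 to 0.385 for the nusA operon. For ribosomal proteins it ran from 1.52e-08, for type 1 fimbriae from 1.57e-06, for Rac from 0.000352 and for cold shock from 0.00871, each up to 0.893. The lists passed in 12, 12, 12, 11, 12, 9 and 7 of the 13, in this order. These 13 include fry, which makes no comparison with other genes. They also include centring on the phage and plasmid probe sets and the added lists, both chosen after seeing the data. Apart from the estimated correlation and fry, the alternatives are refits of camera with the same preset correlation, so the pass counts are not independent. Of the 10 splits of the 6 arrays into 3 and 3, 9 called at least 7 lists, and the highest other called 15. The other splits mix the strains and do not measure chance.

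Between genes, signals of intergenic probe sets that changed were more often higher than lower in nusA11. Many lie near background: 63.2% of intergenic probe sets had a level at or below 7.37, the median of the phage and plasmid probe sets, and 10.8% lay above the highest of these. Of 2886 intergenic probe sets, 18.8% changed: 376 rose and 166 fell, so 69.4% of the changed ones rose, against 47.5% of the changed genes. Upward changes of at least 2-fold numbered 91 and downward ones 46. The largest rise, 4.48 ± 0.20 (limma adjusted p = 1.89e-05, n = 3 per strain), was on the forward strand from position 3494515 to 3494891. It was followed by 3.51 ± 0.17 (adjusted p = 1.97e-05) on the reverse strand from 4242655 to 4242807. The largest falls were -3.18 ± 0.23 (adjusted p = 0.000114) on the forward strand from 4215993 to 4216174 and -3.17 ± 0.36 (adjusted p = 0.000889) on the reverse strand from 3119296 to 3119649. The lower strain levels of these 4 were 6.80, 9.48, 8.26 and 6.90, of which all but the second lay at or below the highest phage and plasmid level, 9.45, so sizes and ranks are not exact. These positions are as the array's identifiers give them, on a build not given in the sources used here. Of the probe sets above that highest level, 66 rose and 42 fell. The split depended on scaling. With each class scaled on its own, which removes a shift between the classes, the contrast with genes shrank. After median centring 57.0% of the changed intergenic probe sets rose (11.4% of all rose and 8.63% fell), against 56.1% of the changed genes, and after cyclic loess 58.1% (11.8% and 8.49%), against 50.4%. With genes and intergenic probe sets scaled together, it was 74.3% against 53.7% after median centring and 71.0% against 45.0% after cyclic loess. Centring on the phage and plasmid probe sets gave 90.0% (24.7% and 2.74%), against 74.6%. Scaling together and this centring were chosen after seeing the data. Without wild-type replicate 1, 11.5% of the probe sets changed, and without wild-type replicate 2, 8.63%. With 1 array left out, 64.3% (without nusA11 replicate 3) to 75.1% (without nusA11 replicate 1) of the changed intergenic probe sets rose. Of the changed genes 44.7% and 43.4% rose in these fits. Without nusA11 replicate 2 the shares were 66.6% and 53.6%. The median differences were then -0.011 over intergenic probe sets and -0.024 over genes, against 0.030 and -0.047 with all arrays.

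**Figure D3:**
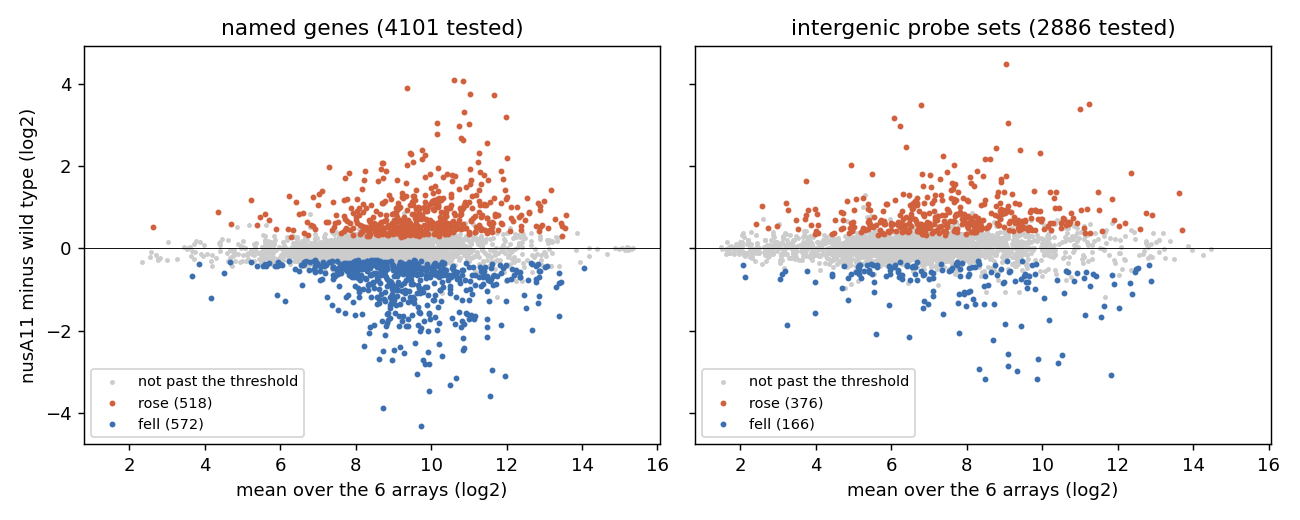
Difference (nusA11 minus wild type, log2, vertical axis) against the mean over the 6 arrays (log2, horizontal axis) for 4101 named genes and 2886 intergenic probe sets. Orange and blue points passed the limma threshold, 518 genes upward and 572 downward, and 376 intergenic probe sets upward and 166 downward.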

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

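The test in this part was chosen only after the result was seen. Outside the comparison of named genes, 244 probe sets with a locus tag could not be tied to 1 current gene. They were fitted and adjusted on their own, in the same way as the intergenic probe sets. Of these, 23 rose and 27 fell in nusA11 (limma), 84 had an unadjusted p under 0.05, and the median difference was -0.06. They are given here because they passed the threshold in data that the comparisons leave out, while 0 of the 59 phage and plasmid probe sets, without a target in this genome, rose (limma; 14 fell, and 21 had an unadjusted p under 0.05). Which transcripts they measure was not analysed here.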

How the results depend on the processing

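Tests chosen only after the result was seen here are the splits for genes, scaling of genes and intergenic probe sets together, centring on the phage and plasmid probe sets, other choices of probe sets and testing with the added lists. The labels do not say whether replicates were separate cultures, and 3 arrays per strain give 10 splits, too few for a share under 0.05. The real split called 1090 genes and the highest other 0, so 1 of 10 called as many. Of the intergenic probe sets it called 18.8% and the highest other 0, again 1 of 10. It called 7 lists while other splits called up to 15, and 9 of 10 called at least 7. Each of the other splits mixes the strains in both groups. The strain difference then widens the spread within groups, so 0 calls there do not measure chance. Part of that difference also stays between the groups, so the list counts do not measure chance either. Without moderation, 634 genes passed, 299 higher and 335 lower, and the cause was not tested. With all 7290 probe sets other than controls in 1 test, 1672 passed, 924 of them higher, because more were tested. Centring on the phage and plasmid probe sets raised all nusA11 values against the wild type, so 260 genes fell, and 24.7% of intergenic probe sets rose and 2.74% fell. Of the 1090 genes, 1072 passed in the same direction with trend and robust moderation, 1014 after median centring, 981 after cyclic loess, 1057 with array weights and 950 with dim genes left out. With 1 symbol per probe set 964 did, without shared probe sets 1076, and with genes and intergenic probe sets scaled together 1033 (median centring) and 1018 (cyclic loess). With 1 array left out, 664 (without wild-type replicate 2) to 1448 (without nusA11 replicate 2) genes passed, 336 to 776 higher and 328 to 672 lower. Of the intergenic probe sets, 8.63% (without wild-type replicate 2) to 18.4% passed, 6.20% to 13.1% higher and 2.43% to 6.58% lower. Without wild-type replicate 1, 11.5% passed, and without wild-type replicate 3, 3.78% fell; why these counts moved was not tested. Of 112 named genes past the threshold, at least 88 still passed in each alternative that measured all of them, and 0 named genes reversed. With an estimated correlation 0 lists passed (camera, 3 at an unadjusted p under 0.05), by fry 9, after cyclic loess 11 and without 1 array 6 to 10; the cause was not tested. Cold shock did not pass by fry (adjusted p = 0.0717) or after centring on the phage and plasmid probe sets, and Rac did not by fry (0.148). With the replicate number as a block, 1004 genes, 20.2% of intergenic probe sets and 7 lists passed, and 105 of the 112 named genes still did. No pairing of the arrays by number was seen: deviations of arrays sharing a number correlated at 0.13, -0.08 and -0.04, and 2 of 6 arrays matched best with their own number. With 3 arrays per strain this cannot exclude pairing. A mean over the probe sets of a gene was not run, since each gene has 1.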

Other observations

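The 13 gene lists in this part, and the tests of ribosomal protein genes, of probe sets without a target and of prophage Rac, the scaling of genes and intergenic probe sets together, and the shares by length and by position opposite to genes, were chosen only after the result was seen. Of 13 glycolysis genes, 10 rose and 1 fell: gpmM, for a phosphoglycerate mutase, rose by 2.97 ± 0.25, pfkA, for phosphofructokinase, by 2.09 ± 0.22 and eno by 1.68 ± 0.13, while fbaB fell by 0.94 ± 0.10. The 3 genes of the fructose operon rose, led by fruK at 2.28 ± 0.26. Other added lists of catabolism fell. This held for 7 of 7 genes of acetate uptake and the glyoxylate shunt, with a median of -3.06, and for 5 of 5 of GABA and glutarate breakdown, with gabT at -2.82 and gabD at -2.80. It also held for 5 of 5 of arginine breakdown, with astC at -2.53, 11 of 11 of phenylacetate breakdown, with paaC at -2.31, and 5 of 5 of glycolate use, with glcD at -2.18. The proline genes putP and putA fell by 2.33 ± 0.12 and 1.93 ± 0.12. The lower strain levels of gpmM, fruK, gabT, gabD, astC, paaC, putP and putA were 8.33 to 9.27. These lie below 9.45, the highest phage and plasmid level, so sizes are not exact. Over the added lists with at least 4 genes, camera adjusted p was 1.89e-06 for glycolysis, 4.88e-07 for acetate, 1.82e-07 for GABA, 1.89e-06 for arginine, 1.32e-09 for phenylacetate and 0.000757 for glycolate. With an estimated correlation these were 0.149 to 0.161.

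Periplasmic respiration with nitrate and nitrite rose as a whole: 14 of 14 nap and nrf genes, among them napB at 2.09 ± 0.16 and napC at 1.72 ± 0.11 (camera adjusted p = 2.47e-13, and 0.149 with an estimated correlation). Its nrfA, nrfB and nrfC are also in the anaerobic list above. Hydrogenase genes split. The 5 maturation genes hypA to hypE rose, from 0.88 for hypE to 1.75 for hypB, and of the other 10 genes, the hyc genes and fhlA, 0 passed in limma and 0 had an unadjusted p under 0.05. The 15 genes together had a camera adjusted p of 0.00286, and 0.149 with an estimated correlation. Of 23 aminoacyl-tRNA synthetase genes 2 rose, serS (0.62 ± 0.18) and thrS (0.61 ± 0.17), or 0 adjusted over the list alone, and 4 had an unadjusted limma p under 0.05. Without nusA11 replicate 2, 6 rose, without wild-type replicate 3, 1 rose, and without any 1 other array these calls were lost. Of 14 purine genes purC rose (0.87 ± 0.10), and of 10 pyrimidine genes pyrG rose (0.58 ± 0.12). With 1 array left out, 2 purine genes rose (nusA11 replicate 3) and 2 pyrimidine genes fell (nusA11 replicate 2). Camera adjusted p of the 3 lists were 0.226, 0.226 and 0.598, and by mixed fry 0.0642, 0.000299 and 0.0509.

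Anaerobic respiration genes were higher and TCA cycle genes lower in nusA11. The tables argue against scaling between arrays as the whole cause: after cyclic loess 30 of 35 anaerobic genes rose and 16 of 16 TCA cycle genes fell. They also argue against 1 aberrant or mislabelled array, since without any 1 array at least 25 anaerobic genes rose and at least 13 TCA cycle genes fell. A difference in growth phase or oxygen supply between the cultures stays open. It may raise growth genes too, and ribosomal protein genes had a median of 0.24 (0.16 without wild-type replicate 3 and 0.33 without wild-type replicate 1). Their list adjusted p was 0.893 by camera with an estimated correlation and 0.170 by fry. These values decide nothing, since a rise of growth genes could not tell growth phase from oxygen supply. An effect of the nusA11 allele itself was not tested, since the growth conditions are not given for either strain.

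Intergenic probe sets that changed were more often higher in nusA11. In 1 fit of all probe sets other than controls, 592 intergenic probe sets changed. Of the 535 that could be matched on intensity to changed gene probe sets, 68.8% rose, against 39.4% to 47.5% in 10000 draws of these. After cyclic loess of both together it was 69.6% against 40.8% to 49.0%, which argues against intensity-dependent scaling as the whole cause; with each class scaled on its own, shares were 58.1% and 50.4% after loess and 57.0% and 56.1% after median centring. A rise of unspecific signal that needs no target is argued against by the 81 phage, plasmid and control probe sets. Their median was -0.19 (bootstrap interval -0.22 to -0.16). Phage and plasmid probe sets have no target in this genome, so they cannot speak to signal that comes from the chromosome itself. Array medians of the phage and plasmid probe sets were 7.37 to 7.53 in the wild type and 7.18 to 7.35 in nusA11. Those of the controls were 6.41 to 6.44 and 6.03 to 6.40, so the strains lay close. The interval, the draws and the permutation below take probe sets as units. They do not measure the spread between arrays. Gene positions were not used: a base with no intergenic probe set on the other strand was taken to lie opposite to a gene. Of the changed probe sets with no such base, 69.4% of 468 rose. Of the 424 among them that could be matched on intensity, 69.3% rose, against 39.4% to 48.6% in matched gene draws. For them, transcription opposite to genes is argued against under this rule. Elsewhere it stays open: in a planned test those over 500 bases rose less than shorter ones (-0.079, permutation p = 0.00250), but it took all probe sets, while the 18.8% that changed make the pattern, and shares that rose among changed long and short ones differed by 0.579 percentage points (bootstrap interval -9.29 to 9.82); a candidate explanation not tested is less termination in nusA11, with transcripts running past gene ends.

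Signals of prophage Rac genes were lower in nusA11. Their median of -0.25 (-0.07 with arrays centred on phage and plasmid probe sets) lies just outside the -0.24 to -0.16 of random draws of as many phage, plasmid and control probe sets, but its own bootstrap interval, -0.31 to -0.21, overlaps them. These draws and this interval take probe sets as units and do not measure the spread between arrays. A change in Rac transcripts and a drift of probe sets without a target cannot be told apart, since these genes lie at the level of such probe sets. Whether the cells carry the prophage, and whether 1 strain lost it, were not tested.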
